A study of Mus musculus with 10 samples.

How the data were processed

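Total RNA from the livers of female non-obese diabetic (NOD) mice, an inbred strain that develops autoimmune diabetes, was sequenced in 10 libraries. The labels gave 4 groups: 1 non-diabetic liver (numbered 2), 3 untreated diabetic livers, 3 livers given an AAV8 vector carrying INS-FUR, and 3 livers given the AAV8/piggyBac vector. AAV8 is a recombinant adeno-associated virus that reaches hepatocytes and stays largely outside the chromosomes. INS-FUR is an insulin sequence carrying sites that the protease furin cleaves, and piggyBac is a transposon system that integrates its cargo into the genome. The labels number the livers within a group but give no further details of the animals, so the p-values measure the spread between these samples, which may be partly technical.

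The authors deposited 9 tables of 48709 genes, each comparing 1 library with the same non-diabetic library, on genome build mm10 per the submitters' processing notes. The aligner, the counting method and the software of the authors' comparisons were not given in the sources used here. Per the file headers, each deposited table held a larger group mean, a log2 fold change, p-values and FDR-adjusted p-values. The headers named no unit for the group mean, and its values showed it to be an RPKM from the authors (a read count scaled by exon length in kilobases and by the library's reads in genes). The deposited log2 fold change equalled the log2 ratio of the 2 RPKM values minus 1 constant per table, which was taken as the authors' rescaling of that library. These constants were 0.36, 0.04 and 0.01 for diabetic libraries 1 to 3, -0.04, -0.07 and 0.01 for the AAV8 libraries, and -0.25, 0.05 and 0.05 for the AAV8/piggyBac libraries. In the authors' deposited tables a fold change was given for 19976, 20083 and 21228 genes of the AAV8 libraries and for 25224 genes of each of the other 6 libraries.

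The RPKM of all 10 libraries was recovered from these columns. A library's value was read directly where it was the larger of the pair, and otherwise computed from the non-diabetic value and the fold change. The rebuilt values gave back the deposited log2 folds within 0.00397 for genes at 1 RPKM or more in both libraries. For values computed from the fold change this agreement is built in. A separate check used genes higher than in the non-diabetic library whose non-diabetic value another table showed. The implied and the shown non-diabetic values agreed closely in 100% of 1435 to 6143 such genes per library. The main values are RPKM after the authors' rescaling ("rescaled RPKM"). Gene positions are those of the tables, and 87.8% of the genes had the same start and end in GENCODE M21, which supplied exon lengths. The tables held no counts. In genes of few reads the RPKM lay on whole-read steps (95.3% to 96.9% of values within 0.1 of a whole number of reads), and these steps gave the number of reads in genes of each library, which limits the precision of low genes. The floor of a gene at 0 was set at 3 reads per library, and it covers counting error only. No 2 libraries of a group differed by as little as sampling noise. The median chi-square per degree of freedom over genes of at least 20 reads was 2.63 for diabetic libraries 2 and 3 and 4.98 to 31.3 for the other pairs. Diabetic libraries 2 and 3 were thus the closest pair (r = 0.996). A difference beyond sampling noise does not by itself show that 2 libraries came from different animals.

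The design fixed before the data were examined set the groups, the 6 comparisons, the 37 gene lists, the rule for naming genes and the first set of alternatives. It planned a count model if the files held counts, and otherwise limma. As the tables held none, limma 3.58.1 in R 4.3.3 was used (lmFit and eBayes with an intensity trend) on log2(rescaled RPKM + 1), with all 10 libraries and 4 groups in 1 fit and no other covariate. Genes with a mean of at least 1 rescaled RPKM were tested (10009 genes), two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Each adjusted p of a gene is limma's. Log2 differences are on the log2(value + 1) scale, which understates the change of low genes. This scale also narrows the spread of values near 0. For genes near 0 in some groups, the shared spread may thus understate that of the other groups. The non-diabetic group has 1 library, which was assumed to vary like the others. Values in the text are means of rescaled RPKM ± SD.

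The lists covered liver metabolism, stress and immune responses, markers of hepatocytes and of other cell types, sex-biased genes, the clock and the respiratory chain, and held 730 genes. Lists with at least 3 tested members (33 of 37) were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and each adjusted p of a list is camera's unless another test is named. Camera with an estimated correlation and fry were alternatives. Within each list, genes were also counted after adjustment over that list. Genes were named by 3 parts of a rule. The first took, among genes with an adjusted p under 0.05, a mean of at least 1 and no overlap between the groups, the 8 largest rises and 8 largest falls, without predicted genes. The second took up to 4 members of each list with the smallest p, and the third always took Ins1, Ins2, Furin, Pck1, G6pc, Igfbp1, Alb and 1 gene that is not reported here. No overlap arises by chance for 10% of genes in 3 against 3 libraries. Genes named for single libraries were chosen after their values were seen.

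Alternatives fixed in advance were median-centred values, no filter, no trend, a pseudocount of 0.1, the replicate number as a block, only the 6 libraries compared, and leaving out each library in turn. Chosen after seeing the data were values without the authors' rescaling, library weights, a clock score as a covariate, and leaving out each library in the list tests. The clock score was the mean log2 value of Arntl, Npas2, Clock and Cry1 minus that of Dbp, Tef, Usp2, Ciart and Per3. The overlap of the comparisons that share the diabetic libraries was set against 100 simulations of unchanged groups.

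The tests were run on simulated data with 200 of 10009 genes changed. Changed genes were drawn from those with a mean log2 value of at least 3, and the noise of a gene had the same spread in all libraries. The shares below thus do not cover lower genes or a library that stands apart. At log2 changes of 1, 2 and 3, the share recovered was 73.1%, 85.1% and 97% for AAV8 against diabetic, 71.6%, 94% and 97% for AAV8/piggyBac against diabetic, 52.2%, 92.5% and 98.5% for AAV8/piggyBac against AAV8, and 35.8%, 73.1% and 87.9% for diabetic against non-diabetic. It was 25.4%, 86.6% and 93.9% for AAV8 against non-diabetic and 32.8%, 82.1% and 83.3% for AAV8/piggyBac against non-diabetic. In the same order 6.1%, 5.9%, 5.8%, 2.2%, 7.4% and 4.3% of the genes called were unchanged ones. In the design of AAV8 against diabetic, the list test called 50 of 50 lists of 25 genes shifted by 0.5 and 0 of 950 unshifted lists. The simulated genes varied independently, so this check cannot show how the list test behaves where the genes of a list move together. The reads of near-identical genes could be split between copies, so the levels of immunoglobulin V genes, Saa1 and Saa2, the Gsta genes, the Cyp3a and Cyp4a genes, the Mup genes, Hamp2, Ces3b and haemoglobin genes are uncertain. The authors' own p-values compare 1 library with 1 library and were not used. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 rebuilt the values and drew the plots.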

Results

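Liver gene expression was measured in 1 non-diabetic NOD liver, 3 untreated diabetic livers, 3 livers with the non-integrating AAV8 vector and 3 livers with the integrating AAV8/piggyBac vector. The non-diabetic library held 76.6 M reads (M, the mega prefix) in genes. The diabetic libraries held 69.5, 77.1 and 73.9 M, the AAV8 libraries 70.8, 85.7 and 93.6 M, and the AAV8/piggyBac libraries 66.9, 66.1 and 78.5 M. Diabetic library 1 stood apart, with a correlation across genes of 0.933 and 0.934 to diabetic libraries 2 and 3 against 0.996 between those libraries, and with 23965 genes above 0 against 19057 to 19991 in the other libraries. Genes are not independent replicates. No values of the non-diabetic liver carry a replicate error, since it was 1 library.

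Insulin transcript was present in all treated livers. Ins1 (ENSMUSG00000035804, chromosome 19, 52264323 to 52265456), which encodes a mouse preproinsulin, was 11.2 ± 2.93 rescaled RPKM in AAV8 livers and 29.3 ± 14.2 in AAV8/piggyBac livers (SD, n = 3 each). It had 0 reads in the non-diabetic and the 3 diabetic libraries. The AAV8 libraries held 795, 1238 and 846 Ins1 reads and the AAV8/piggyBac libraries 1617, 3237 and 1409. Measured as RPKM against the highest floor of 3 reads in a diabetic library (0.0406), Ins1 was at least 268-fold higher in AAV8 livers and at least 703-fold higher in AAV8/piggyBac livers. The rise passed against diabetic liver for AAV8 (adjusted p = 0.00243) and AAV8/piggyBac (adjusted p = 0.00149), in 3 of 3 libraries each. The AAV8/piggyBac mean was 2.61 times the AAV8 mean, a difference that did not pass (log2 1.23, SE 0.31, adjusted p = 0.784). Ins2, the other mouse insulin gene, stayed at or below 0.0979 RPKM, with 9 reads in diabetic library 1 and 1 read each in AAV8 library 1 and AAV8/piggyBac library 2. Furin, whose protease cleaves proinsulin at the engineered sites, was 41.5 in non-diabetic liver, 46.6 ± 6.58 in diabetic, 45.8 ± 1.30 in AAV8 and 46.7 ± 7.69 in AAV8/piggyBac livers. A value per gene cannot tell vector-derived reads from reads of the mouse gene itself.

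**Figure D1:**
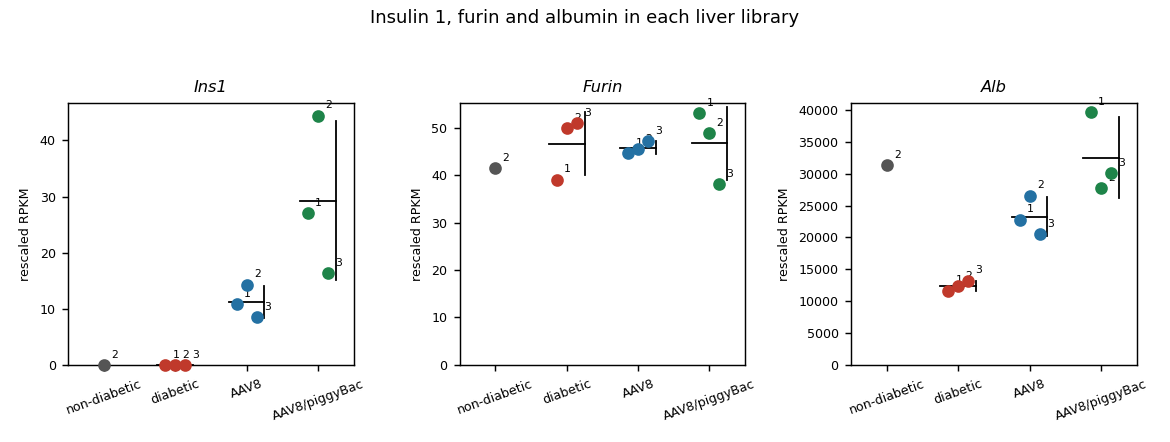
Rescaled RPKM (linear axes) of Ins1, Furin and Alb in each liver library by group, with numbered dots for libraries and lines for the group mean ± SD. Ins1 was 0 in the non-diabetic and diabetic libraries and lay between 8.46 and 44.4 in the 6 treated libraries.

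The comparison of diabetic with non-diabetic liver gives the state that the vectors were meant to treat. Genes of lipid synthesis were lower in the diabetic livers than in the 1 non-diabetic liver. Scd1, the stearoyl-CoA desaturase, was 1849 in non-diabetic and 47.0 ± 61.3 in diabetic livers (n = 3), and Sc5d, an enzyme of late cholesterol synthesis, 297 and 55.0 ± 14.6. Pck1, which encodes the gluconeogenic enzyme PEPCK, was 226 and 1147 ± 536, and G6pc, glucose-6-phosphatase, was 164 and 155 ± 66.1. Igfbp1, an insulin-repressed binding protein, was 81.8 and 99.1 ± 42.2. None of these genes passed alone (adjusted p = 0.275 for Scd1, 0.0993 for Sc5d and 0.653 for Pck1). Only 1 of 10009 genes did: Ces3b, a carboxylesterase (ENSMUSG00000062181, chromosome 8, 105083753 to 105093929), fell from 151 to 17.2 ± 2.05 (log2 -3.07, SE 0.28, adjusted p = 0.0208), lower in 3 of 3 libraries. At an unadjusted p under 0.05 there were 755 genes. The Ces3b call was lost without diabetic library 2 or 3 (highest adjusted p = 0.121), and the count was 9 without diabetic library 1. Without the authors' rescaling the median log2 difference of all genes was 0.115 (0.006 with it).

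Lists of lipid genes differed between the diabetic livers and the 1 non-diabetic liver, which does not separate diabetes from the state of that animal. The cholesterol synthesis list fell, with all 25 members lower (median log2 -1.63, adjusted p = 2.63e-13), as did glycolysis and lipogenesis, with all 22 members lower (median -1.30, adjusted p = 9.15e-10). Each had adjusted p = 0.682 with an estimated correlation. Over all genes 0 members of either passed, and 4 and 5 fell when adjusted over the list alone. Hepatocyte markers fell (median -0.67, adjusted p = 1.14e-06), with 0 members over all genes and 5 of 25 adjusted over the list alone. Alb, serum albumin, was 31308 and 12421 ± 783, and Foxa2, a hepatocyte transcription factor, 24.0 and 8.73 ± 1.30. Gluconeogenesis and fasting genes rose (median 0.44, adjusted p = 0.00408), as did fatty acid oxidation (median 0.22, adjusted p = 0.0129), targets of the oxidative stress factor Nrf2 (median 0.87, adjusted p = 0.000135) and proliferation genes (median 0.64, adjusted p = 0.00139). These 4 lists had 0 members over all genes and 0, 1, 0 and 0 adjusted over the list alone. For the hepatocyte markers and these 4 lists, adjusted p = 0.682 with an estimated correlation. Without diabetic library 1 the gluconeogenesis median was 0.83 (0.27 without library 2), that of fatty acid oxidation 0.38 and that of Nrf2 targets 0.45. With a score of clock genes as a covariate the lipogenesis median was -0.75 (adjusted p = 0.00107) and that of proliferation 0.97, and the gluconeogenesis and fatty acid oxidation calls were lost (adjusted p = 0.14 and 0.359).

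Calls of 8 further lists in this comparison depended on single libraries, and each list had 0 members over all genes. Without diabetic library 1, fetal liver genes (median 0.71, adjusted p = 0.0172), p53 targets (0.82, 0.00332), immediate early genes (0.67, 0.0172) and female-biased genes (-0.72, 0.0172) were no longer called, at adjusted p of 0.917, 0.176, 0.948 and 0.0657. Adjusted over the list alone, 0, 0, 1 lower and 1 lower of their members passed. Drug-metabolising P450 genes (median 0.34, adjusted p = 0.0232), male-biased genes (-0.47, 0.0192) and mitochondrial transcripts (0.35, 0.0172) lost their calls without diabetic library 2 (0.0809, 0.084 and 0.147) or 3 (0.0966, 0.0757 and 0.0908), and nuclear respiratory chain genes (0.21, 0.00408) without library 2 (0.156). Without library 1 these 4 calls were stronger, with medians of 1.15, -1.15, 0.68 and 0.38 (adjusted p = 0.00261, 0.000707, 2.31e-05 and 3.38e-06). Of these 4 lists only the P450 list had a member adjusted over the list alone (1). Adjusted p = 0.792 with an estimated correlation for the fetal, immediate early, P450, mitochondrial and nuclear respiratory lists, and 0.682 for the other 3. Without the authors' rescaling the fetal, P450 and immediate early calls were also lost (adjusted p = 0.137, 0.103 and 0.137). Interferon response and antigen presentation genes were not called with all libraries (median 0.21 and 0.18), but were called in opposite directions as single libraries were left out. Their medians were -0.63 and -0.38 (adjusted p = 1.14e-09 and 0.00649) without diabetic library 1, 0.58 and 0.43 (0.000793 and 0.0174) without library 2, and 0.61 and 0.50 (0.000942 and 0.0133) without library 3. Macrophage markers (0.28, 0.0834) were called higher without library 2 (0.50, 0.00997) or 3 (0.52, 0.00222). None of the list calls in any of the 6 comparisons held with an estimated correlation.

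**Figure D2:**
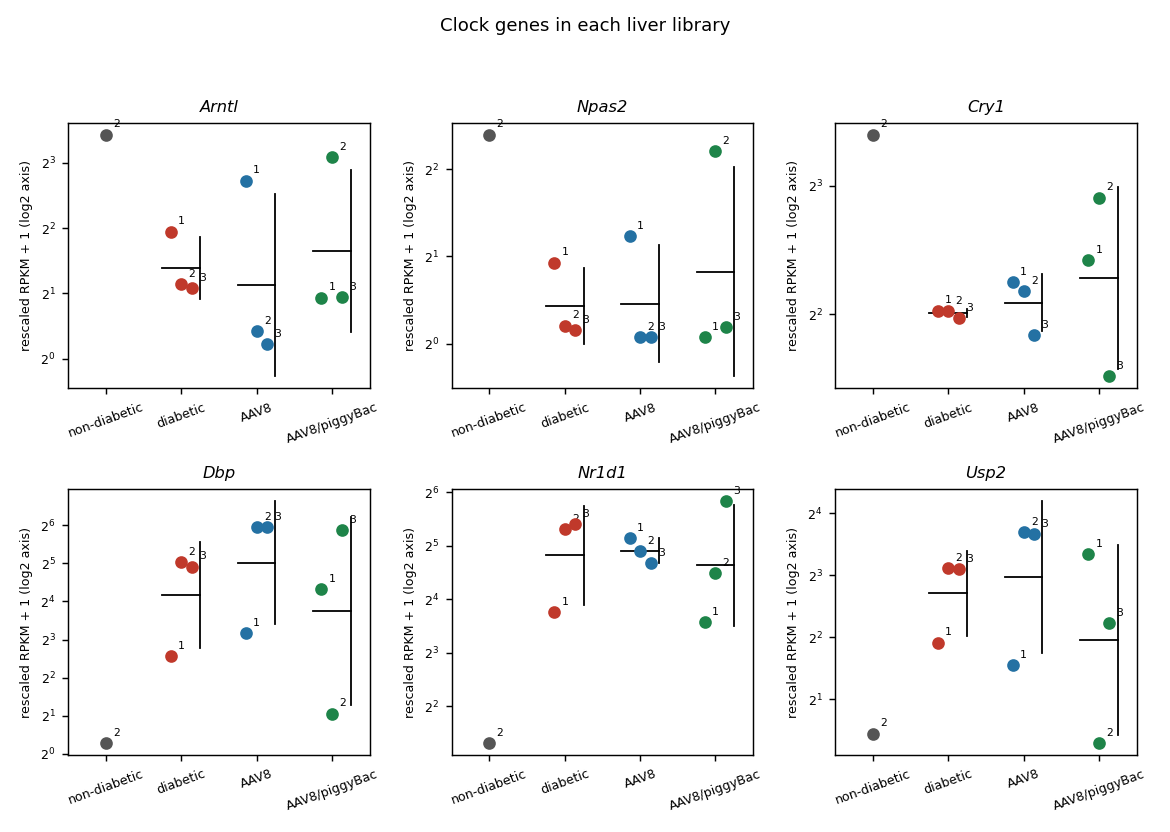
Rescaled RPKM + 1 (log2 axes) of 6 clock genes in each liver library by group, with numbered dots for libraries, a horizontal line for the mean of the log2 values and a vertical line for ± 1 SD. The non-diabetic library and AAV8/piggyBac library 2 have high Arntl (9.79 and 7.49) and low Dbp (0.226 and 1.08), and AAV8 library 3 has Arntl at 0.172.

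Clock genes differed between libraries of the same group. The clock score was 2.31 in the non-diabetic library, 1.86 in AAV8/piggyBac library 2, 0.351 in AAV8 library 1 and -0.142 in diabetic library 1, and between -3.12 and -1.81 in the other 6 libraries. The non-diabetic library thus had a clock state unlike most libraries it was compared with. In diabetic against non-diabetic liver, the clock score as a covariate also ended the calls of P450, male-biased, immediate early, mitochondrial and nuclear respiratory genes (adjusted p = 0.945, 0.412, 0.201, 0.211 and 0.0849), and the fetal median was 1.28 with it. In diabetic library 1, p53 and interferon genes were also far from the other diabetic libraries. Cdkn1a, the cell cycle inhibitor p21, was 78.1 there against 3.54 and 4.05, and Igtp, an interferon-induced GTPase, 286 against 9.13 and 9.22. Gsta1, a glutathione transferase, was 65.7 against 3.58 and 4.64, and Afp, alpha-fetoprotein of fetal liver, 26.2 against 0.737 and 0.848.

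The comparison of AAV8 with diabetic liver asks what the non-integrating vector changed. Plasma cell transcripts rose. Ighg1 (ENSMUSG00000076614, chromosome 12, 113325240 to 113330523), the constant region of IgG1, was 0.194 ± 0.0474 in diabetic and 90.3 ± 48.9 in AAV8 livers (n = 3 each), and Igkc, the kappa light chain, 18.9 ± 10.6 and 380 ± 179. Jchain, which joins antibody multimers, was 0.843 ± 0.501 and 11.8 ± 4.52. Srebf1 (chromosome 11, 60199089 to 60222581), the transcription factor of lipogenesis, rose from 29.5 ± 3.62 to 78.7 ± 7.20, and Sc5d from 55.0 ± 14.6 to 183 ± 43.2. Hspb1, a small heat shock protein, fell from 33.6 ± 9.80 to 7.69 ± 2.48, Slc25a22, a mitochondrial glutamate carrier, from 79.6 ± 5.66 to 38.2 ± 6.88, and Tbrg1 from 11.2 ± 1.31 to 6.42 ± 0.103. In limma 35 genes changed (32 rose and 3 fell, and 1050 had an unadjusted p under 0.05), of which 18 were immunoglobulin genes or Jchain. The log2 difference was 6.13 (SE 0.34, adjusted p = 8.87e-05) for Ighg1, 4.35 (SE 0.56, adjusted p = 0.0223) for Igkc, 2.77 (SE 0.30, adjusted p = 0.0089) for Jchain, 1.39 (SE 0.20, adjusted p = 0.0363) for Srebf1, 1.72 (SE 0.25, adjusted p = 0.0363) for Sc5d, and -1.99 (SE 0.28, adjusted p = 0.0363) for Hspb1. All 3 AAV8 libraries lay on the same side of all 3 diabetic libraries for each of these. The naming rule required this of the largest rises and falls, so for them it adds no evidence.

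Leaving out single libraries moved this AAV8 count to 37 and 9 without diabetic libraries 1 and 2, 14 without diabetic library 3, and 71, 21 and 25 without AAV8 libraries 1, 2 and 3. Across these settings 9 genes were called each time: Ighg1, Ighv1-76, Ighv8-12, Ighv8-8, Igkv12-44, Igkv3-12, Igkv3-7, Ins1 and Jchain. Some of these lay near 0 outside the AAV8 livers, as Ighg1 did (0.141 to 0.232 in diabetic and 54.8 to 146 in AAV8 libraries). There the shared spread may understate that within AAV8 livers, so their SE and p-values may be too small. Igkc lost its call without diabetic library 2 or AAV8 library 2 (highest adjusted p = 0.0903), Sc5d and Hspb1 without diabetic library 2 or 3 or AAV8 library 2 or 3 (0.18 and 0.162), and Srebf1 without any 1 of the 6 libraries (0.174). Slc25a22 kept its call only without AAV8 library 1 (0.18 at most in the others), and Tbrg1 only without diabetic library 1 (0.174 at most). With only these 2 groups in the fit Hspb1, Slc25a22, Tbrg1 and Sc5d lost their calls (highest adjusted p = 0.115). Without the authors' rescaling the median log2 difference of all genes was -0.148 (-0.01 with it), and 33 genes were called, 26 higher and 7 lower.

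Plasma cell, lipid synthesis and acute-phase lists rose in AAV8 against diabetic liver. B and plasma cell markers rose (median log2 2.39, adjusted p = 2.59e-18), with 7 of 9 tested members over all genes and 9 adjusted over the list alone, and adjusted p = 0.22 with an estimated correlation. The 7 were Igkc, Iglc2, Ighg2b, Ighg2c, Igha, Jchain and Mzb1, which are among the genes called singly. The sum of 5 B cell surface markers overlapped between the groups, at 1.18 to 2.44 in AAV8 and 0.798 to 1.4 in diabetic livers. Cholesterol synthesis (25 of 25 members higher, median 1.46, adjusted p = 2.53e-15) and glycolysis and lipogenesis (21 of 22 higher, median 1.16, adjusted p = 6.32e-13) rose, each with 1 member over all genes, and with 7 and 12 adjusted over the list alone. Insig1, a sterol sensor, was 46.7 ± 27.9 in diabetic and 172 ± 39.6 in AAV8 livers, and Scd1 47.0 ± 61.3 and 1544 ± 944 (adjusted p = 0.0746). Acute-phase genes rose (median 1.04, adjusted p = 6.46e-06, 0 over all genes, 5 of 22 adjusted over the list alone), with a median of 0.63 (adjusted p = 5.4e-05) with the clock score as a covariate. The near-identical serum amyloid genes Saa1 and Saa2 were 43.2 ± 54.3 and 17.0 ± 22.0 in diabetic livers and 2019 ± 474 and 1376 ± 318 in AAV8 livers, and did not pass (adjusted p = 0.109 and 0.0707). For these 3 lists adjusted p = 0.739 with an estimated correlation.

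Other AAV8 list calls against diabetic liver moved with diabetic library 1. Hepatocyte markers (median 0.53, adjusted p = 7.1e-06, 0 over all genes, 2 of 25 adjusted over the list alone) and female-biased genes (0.78, 0.0014, 0 and 0 of 15) rose, and p53 targets fell (-0.94, 0.00012, 0 over all genes, and 7 lower and 1 higher of 17 adjusted over the list alone). Adjusted p = 0.739 with an estimated correlation for each of these 3, and without diabetic library 1 their medians were 0.23, 0.21 and -0.46. Interferon response genes were lower (median -0.52, adjusted p = 0.00645, 0 and 0 of 31 adjusted over the list alone, adjusted p = 0.926 with an estimated correlation), but higher without diabetic library 1 (median 0.34, adjusted p = 4.89e-06). The median was -0.98 without diabetic library 2 and -0.95 without library 3, and without the authors' rescaling the call was lost (adjusted p = 0.469). Calls of ribosomal proteins (0.18, 0.0014), Nrf2 targets (-0.58, 3.83e-05), fetal liver genes (-0.39, 0.0258) and immediate early genes (-0.68, 0.00236) were lost without diabetic library 1 (adjusted p = 0.171, 0.0562, 0.367 and 0.758). The fetal median was then 0.10, and that call was also lost without AAV8 library 2 (0.0818). The urea cycle call (-0.35, 0.0423) was lost without diabetic library 2 or 3 (0.232 and 0.181) or AAV8 library 2 or 3 (0.274 and 0.0571), and its median was -0.71 (0.000402) without diabetic library 1 and -0.54 without AAV8 library 1. Other medians grew to -0.94 for Nrf2 targets, -0.69 for fetal genes and 0.30 for ribosomal proteins without diabetic library 2, and to -0.66 and -0.69 for fetal genes without diabetic library 3 and AAV8 library 1. The ribosomal median was 0.11 without AAV8 library 2. These 5 lists had 0 members over all genes and, adjusted over the list alone, 1 lower immediate early gene and 0 others. Adjusted p = 0.739 with an estimated correlation for Nrf2 targets and 0.914 for the other 4. Without rescaling the fetal, urea cycle and immediate early calls were also lost (0.291, 0.101 and 0.0926).

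The comparison of AAV8/piggyBac with diabetic liver asks what the integrating vector changed. Lipid synthesis genes rose. Scd1 (chromosome 19, 44394451 to 44407709) rose from 47.0 ± 61.3 to 4576 ± 3158 (n = 3 each), and Srebf1 from 29.5 ± 3.62 to 83.8 ± 21.04. Mlxipl, which encodes the glucose-responsive factor ChREBP, rose from 11.5 ± 2.44 to 28.0 ± 3.81, Sc5d from 55.0 ± 14.6 to 222 ± 27.9, and Alb from 12421 ± 783 to 32511 ± 6325. Hamp2, a hepcidin gene, rose from 7.97 ± 1.23 to 296 ± 182, and Ces3b from 17.2 ± 2.05 to 66.1 ± 10.8. Ren1, the renin gene, fell from 16.8 ± 5.25 to 0.461 ± 0.151, Slc25a22 from 79.6 ± 5.66 to 19.5 ± 0.724, Egln3, an oxygen-sensing hydroxylase, from 25.7 ± 7.61 to 3.56 ± 0.602, Hspb1 from 33.6 ± 9.80 to 7.27 ± 1.58, and Acsf2, an acyl-CoA synthetase, from 110 ± 9.20 to 37.0 ± 12.7. In limma 45 genes changed (32 rose and 13 fell, and 1528 had an unadjusted p under 0.05). The log2 difference was 7.18 (SE 0.98, adjusted p = 0.0293) for Scd1, 1.45 (SE 0.20, adjusted p = 0.0293) for Srebf1, 1.37 (SE 0.21, adjusted p = 0.0408) for Alb, -3.57 (SE 0.49, adjusted p = 0.0293) for Ren1 and -1.98 (SE 0.16, adjusted p = 0.00355) for Slc25a22, with all 3 treated libraries beyond all 3 diabetic ones. For the largest rises and falls the naming rule required this separation.

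Leaving out single libraries moved this AAV8/piggyBac count to 208 (97 higher and 111 lower) without diabetic library 1, 2 without diabetic library 2 or 3, and 5, 16 and 34 without AAV8/piggyBac libraries 1, 2 and 3. The genes called each time were Ins1 and Slc25a22. Scd1, Srebf1 and Sc5d lost their calls without diabetic library 2 or 3 or AAV8/piggyBac library 1 or 2 (highest adjusted p = 0.157, 0.157 and 0.154), Ces3b without diabetic library 2 or 3 or AAV8/piggyBac library 1 (0.101), and Hamp2 without diabetic library 2 or 3 (0.131). Acsf2 lost its call without diabetic library 2 or 3 or AAV8/piggyBac library 1 or 3 (0.212), and Mlxipl, Alb, Ren1, Egln3 and Hspb1 without any 1 library other than diabetic library 1 (0.157, 0.203, 0.149, 0.166 and 0.157). With only these 2 groups in the fit Scd1, Srebf1, Mlxipl, Alb, Hspb1 and Acsf2 lost their calls (highest adjusted p = 0.097). Without the authors' rescaling the median of all genes was -0.157 (-0.01 with it) and 95 genes were called, 30 higher and 65 lower.

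**Figure D3:**
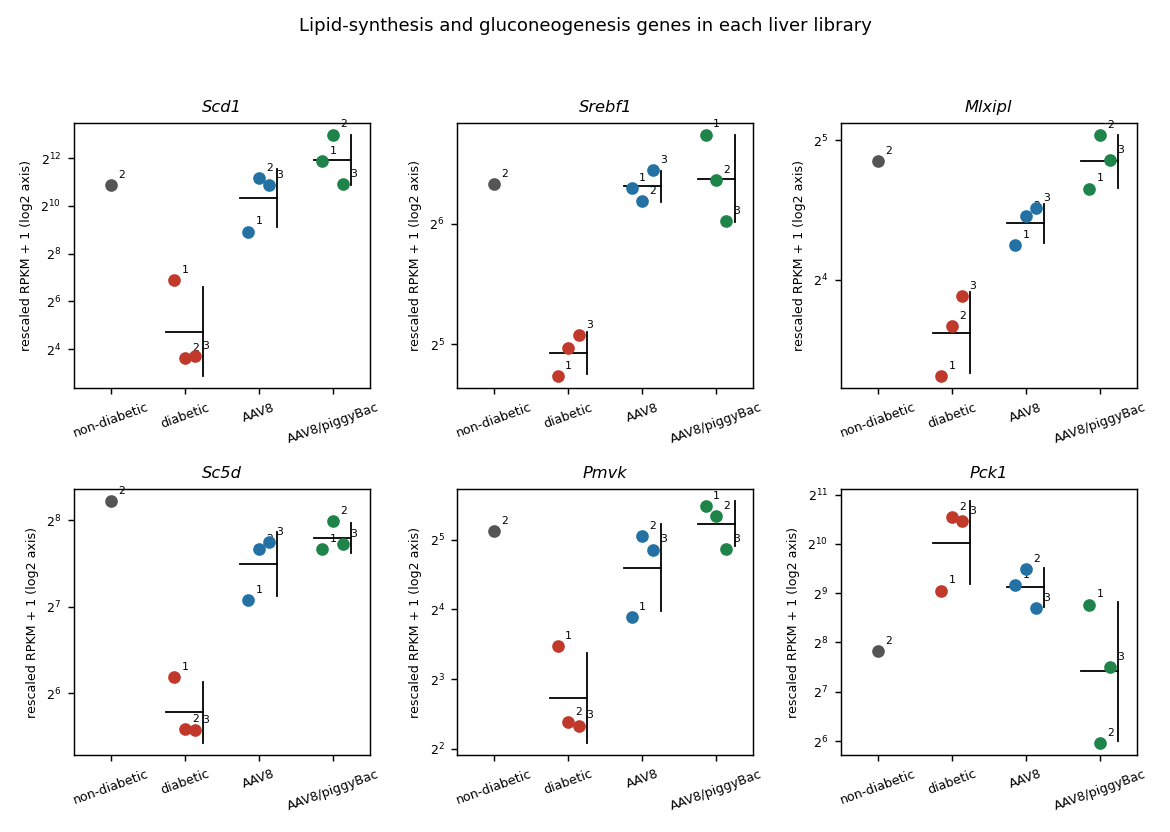
Rescaled RPKM + 1 (log2 axes) of Scd1, Srebf1, Mlxipl, Sc5d, Pmvk and Pck1 in each liver library by group, with numbered dots for libraries, a horizontal line for the mean of the log2 values and a vertical line for ± 1 SD. Scd1 is 11.2 to 118 in the diabetic libraries and 1918 to 8067 in the AAV8/piggyBac libraries.

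Gene groups in AAV8/piggyBac against diabetic liver moved between lipid synthesis and fasting metabolism. Glycolysis and lipogenesis rose (22 of 22 members higher, median log2 1.77, adjusted p = 1.69e-16), with 5 members over all genes and 14 adjusted over the list alone, and cholesterol synthesis rose (25 of 25 higher, median 1.65, adjusted p = 1.36e-14), with 2 and 16. Hepatocyte markers (median 0.55, adjusted p = 3.86e-08) rose, with 1 of 25 members over all genes and 12 adjusted over the list alone. Gluconeogenesis and fasting genes fell (median -0.93, adjusted p = 3.37e-06), with 0 of 18 over all genes and 5 adjusted over the list alone. Pck1 was 1147 ± 536 in diabetic and 226 ± 191 in AAV8/piggyBac livers (adjusted p = 0.137), G6pc 155 ± 66.1 and 29.2 ± 26.9 (adjusted p = 0.106) and Igfbp1 99.1 ± 42.2 and 39.4 ± 28.9. Urea cycle and amino acid catabolism (median -1.0, adjusted p = 1.1e-06, 0 and 3 of 20 adjusted over the list alone), fatty acid oxidation (-0.42, 0.000629, 0 and 3 of 24) and mitochondrial transcripts (-0.67, 4.47e-06, 0 and 0 of 13) fell. Oat, an ornithine-degrading enzyme, was 972 ± 504 and 87.3 ± 56.0. For these 7 lists adjusted p = 0.543 with an estimated correlation. AAV8/piggyBac library 2 stood apart in lipogenesis and clock genes, with Elovl6, a fatty acid elongase, at 407 against 18.2 and 15.4, and without it the lipogenesis median was 1.14 and that of the urea cycle -0.58.

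Further lists rose or fell in AAV8/piggyBac against diabetic liver. Ribosomal proteins (median 0.42, adjusted p = 8.53e-10), B and plasma cell markers (0.65, 0.00158) and female-biased genes (0.75, 0.00229) rose, with 0 members each over all genes and 1, 2 and 1 adjusted over the list alone. Adjusted p = 0.543 with an estimated correlation for each, and without diabetic library 1 the medians were 0.26, 0.41 and 0.43 (0.43 for plasma cell markers without AAV8/piggyBac library 1). Nuclear respiratory chain genes fell (-0.37, 1.28e-06, 0 and 0 of 25 adjusted over the list alone, adjusted p = 0.593 with an estimated correlation, median -0.21 without diabetic library 2). Calls of proliferation (-0.51, 0.00469), p53 targets (-0.67, 0.00639), Nrf2 targets (-0.52, 9.95e-05) and immediate early genes (-0.39, 0.0178) were lost without diabetic library 1 (adjusted p = 0.1, 0.357, 0.0898 and 0.782). Proliferation and immediate early genes also lost theirs without AAV8/piggyBac library 2 (0.0535 and 0.528). The call of acute-phase genes (0.40, 0.0143) was lost without diabetic library 3 (0.061) or AAV8/piggyBac library 1 (0.948), where Saa1 was 419 against 19.8 and 19.5. The P450 call (-0.52, 0.0189) was lost without diabetic library 2 or 3 (0.0717 and 0.0849) or AAV8/piggyBac library 2 (0.508). Other medians grew: Nrf2 targets to -0.88 and -0.81 without diabetic libraries 2 and 3, immediate early genes to -0.61 without diabetic library 3 or AAV8/piggyBac library 1, acute-phase genes to 0.89 and 0.63 without AAV8/piggyBac libraries 2 and 3, and P450 genes to -0.80 and -1.02 without diabetic library 1 and AAV8/piggyBac library 1. That of p53 targets was -0.33 without AAV8/piggyBac library 3. These 6 lists had 0 members over all genes, and adjusted over the list alone 0 proliferation genes, 7 lower and 1 higher p53 targets, 6 lower Nrf2 targets, 1 lower immediate early gene, 1 higher acute-phase gene and 2 lower P450 genes. In the same order adjusted p = 0.593, 0.593, 0.543, 0.727, 0.727 and 0.688 with an estimated correlation. Without rescaling the p53, P450 and immediate early calls were also lost (0.116, 0.155 and 0.241). Interferon response genes were not called (-0.32, 0.146), but were called higher without diabetic library 1 (0.56, 1.18e-08) and lower without diabetic library 2 (-0.73, 6.19e-05) or 3 (-0.72, 4.46e-05) or AAV8/piggyBac library 3 (-0.56, 0.0156). Antigen presentation genes (0.01, 0.892) were called higher without diabetic library 1 (0.41, 3.91e-05), and macrophage markers (-0.10, 0.581) lower without AAV8/piggyBac library 3 (-0.49, 0.0153).

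Both vectors changed 14 genes in the same direction against diabetic liver. They were Ins1, Srebf1, Sc5d, Hamp2, Ces3b, Mid1ip1, Paox, Adra1b, Cmah, Spry4, Slc22a30, Haus7, Hspb1 and Slc25a22, of which Hspb1 and Slc25a22 fell, and 0 genes changed in opposite directions. Unchanged groups simulated against the same controls gave 0.01 genes up in both and 0 down in both, and independent lists would share 0.102 up and 0.0039 down. The covariance of the log2 differences was 0.130 against 0.0394 in the simulations (95th percentile 0.148), a difference of 0.0901, and r across genes was 0.731 against 0.478 (95th percentile 0.948). Both observed values lay below the 95th percentile of the simulations. Genes are not independent replicates. The count was 22 without diabetic library 1 and 1 without library 2 or 3. The 3 diabetic libraries cannot be split, so part of the excess may come from the shared controls.

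The comparison of AAV8/piggyBac with AAV8 liver asks how the vectors differ. Plasma cell transcripts were lower with AAV8/piggyBac. Ighg1 was 90.3 ± 48.9 in AAV8 and 0.799 ± 0.546 in AAV8/piggyBac livers (n = 3 each), Jchain 11.8 ± 4.52 and 1.28 ± 0.393, and the variable-region genes Igkv12-44 51.7 ± 7.35 and 1.38 ± 0.752, Ighv8-12 37.9 ± 24.0 and 0.0848 ± 0.0733, and Ighv1-76 11.5 ± 2.55 and 0.0919 ± 0.0460, whose reads other variable-region genes may share. In limma 10 genes changed and all fell (395 had an unadjusted p under 0.05), each of them an immunoglobulin gene or Jchain. These 395 of 10009 genes are a share below the 0.05 that unchanged genes would give, so they show no excess. The log2 difference was -5.58 (SE 0.34, adjusted p = 0.000196) for Ighg1, -4.50 (SE 0.26, adjusted p = 0.000173) for Igkv12-44 and -2.44 (SE 0.30, adjusted p = 0.0267) for Jchain, lower in 3 of 3 libraries. For the largest falls the naming rule required no overlap between the groups. Without each library in turn the count was 7 to 14 (7 without AAV8/piggyBac library 2 was the only one under 9), and 7 genes were called each time, Ighg1 and 6 variable-region genes. Jchain lost its call without any 1 of these 6 libraries except AAV8 library 3 (highest adjusted p = 0.152), and with only these 2 groups in the fit (0.0684). Saa1 was 2019 ± 474 and 153 ± 230 (adjusted p = 0.676). Creb3l3, a fasting-response factor, was 75.1 ± 7.47 and 47.2 ± 2.34 (adjusted p = 0.465).

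**Figure D4:**
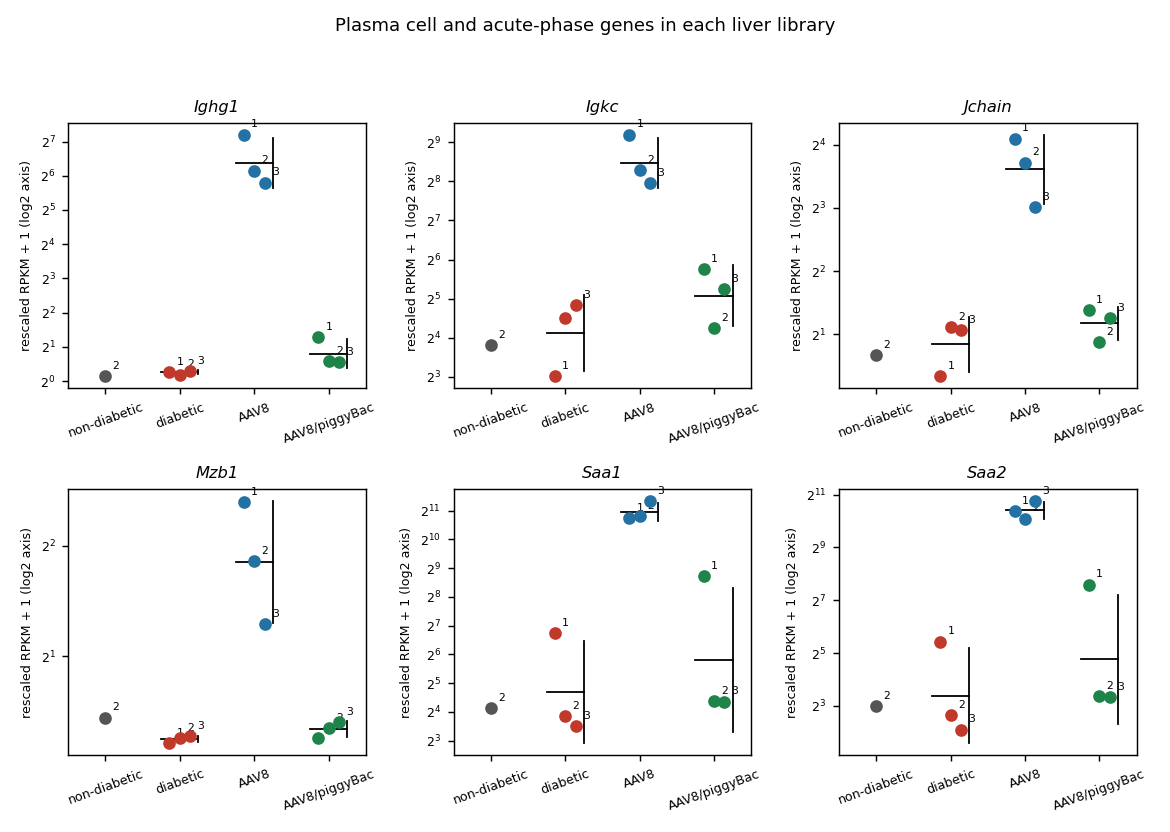
Rescaled RPKM + 1 (log2 axes) of 4 plasma cell genes and of Saa1 and Saa2 in each liver library by group, with numbered dots for libraries, a horizontal line for the mean of the log2 values and a vertical line for ± 1 SD. Ighg1 is 54.8 to 146 in the AAV8 libraries and at most 1.43 in every other library.

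As a group, B and plasma cell markers fell in AAV8/piggyBac against AAV8 liver (median log2 -1.73, adjusted p = 6.97e-18, 1 of 9 members over all genes and 8 adjusted over the list alone, adjusted p = 0.233 with an estimated correlation). Mitochondrial transcripts (median -0.74, adjusted p = 1.64e-11, 13 of 13 lower), gluconeogenesis genes (-0.49, 3.7e-06, 17 of 18 lower) and fatty acid oxidation genes (-0.36, 3.92e-06, 21 of 24 lower) fell, each with adjusted p = 0.567 with an estimated correlation. Urea cycle genes (-0.62, 8.77e-07, 20 of 20 lower) and nuclear respiratory chain genes (-0.24, 2.53e-06, 25 of 25 lower) fell and ribosomal proteins rose (0.24, 8.77e-07, 24 of 25 higher), each with adjusted p = 0.608 with an estimated correlation. In these 6 lists 0 members passed over all genes, and 1 gluconeogenesis gene did when adjusted over the list alone. The urea cycle median was -0.40 without AAV8 library 1 and -0.23 without AAV8/piggyBac library 2. G6pc was 93.4 ± 41.8 in AAV8 and 29.2 ± 26.9 in AAV8/piggyBac livers, and mt-Co1, a subunit of complex IV, 12228 ± 2460 and 8134 ± 1410.

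Single libraries ended 9 list calls between the vectors, where 0 members passed over all genes. Lipogenesis (median 0.46, adjusted p = 0.000159) lost its call without AAV8 library 1 (0.204) or AAV8/piggyBac library 2 (0.968), hepatocyte markers (0.13, 0.00661) without AAV8 library 1 (0.0809) or AAV8/piggyBac library 1 (0.559), and proliferation (-0.31, 0.0359) without AAV8 library 1 (0.487) or AAV8/piggyBac library 2 or 3 (0.34 and 0.109). The unfolded protein response call (0.10, 0.0338) was lost without AAV8 library 2 or 3 (0.122 and 0.0662) or AAV8/piggyBac library 1 or 2 (0.117 and 0.924), and the erythroid call (-0.71, 0.0221) without AAV8 library 3 (0.124) or AAV8/piggyBac library 1 (0.411), whose summed haemoglobin was 0.381 RPKM against 7.45 to 19.8 in the other libraries. Endothelial markers (-0.33, 0.00504) lost their call without AAV8/piggyBac library 1 (0.736), acute-phase genes (-0.44, 0.00661) without AAV8 library 3 (0.0735) or AAV8/piggyBac library 2 or 3 (0.918 and 0.168), P450 genes (-0.55, 0.000752) without AAV8/piggyBac library 2 (0.468), and bile acid genes (-0.14, 0.021) without AAV8 library 2 (0.0694) or AAV8/piggyBac library 2 (0.372). Some medians grew: hepatocyte markers to 0.25 without AAV8 library 2, the unfolded protein response to 0.19 without AAV8 library 1, and acute-phase and bile acid genes to -0.80 and -0.29 without AAV8/piggyBac library 1. Without AAV8/piggyBac library 3 those of hepatocyte markers, the unfolded protein response and erythroid markers were 0.28, 0.33 and -1.15. Adjusted over the list alone 2 acute-phase genes fell and 0 members of the other 8 lists passed. Adjusted p = 0.608 with an estimated correlation for lipogenesis, erythroid, endothelial and P450 genes, and 0.699 for the other 5. The proliferation call was also lost without rescaling (0.0526). With the clock score as a covariate the unfolded protein response, acute-phase and bile acid calls were lost (0.556, 0.0931 and 0.179), and the lipogenesis and P450 medians were 0.29 and -0.27.

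Against the non-diabetic liver, few genes of the treated livers passed. In AAV8 livers 8 genes rose (325 had an unadjusted p under 0.05): Ins1 and 7 immunoglobulin genes, among them Ighg1 at 0.106 in non-diabetic liver (log2 6.24, SE 0.48, adjusted p = 0.00138) and Igkv12-44 at 0.101 (log2 5.57, SE 0.37, adjusted p = 0.000794), in 3 of 3 libraries each. In AAV8/piggyBac livers Ins1 alone rose (adjusted p = 0.0258, and 198 genes had an unadjusted p under 0.05). The 325 and 198 genes of 10009 are shares below the 0.05 that unchanged genes would give, so they show no excess. The Ins1 call was lost for AAV8 (adjusted p = 0.0359) without AAV8 library 1 or 2 or diabetic library 1 (0.109, 0.0862 and 0.0718), and for AAV8/piggyBac without AAV8/piggyBac library 1 or diabetic library 1 (highest 0.151). The AAV8 count was 13 without AAV8 library 3 and 6 without diabetic library 1, and the AAV8/piggyBac count 2 without AAV8/piggyBac library 2 and 0 without diabetic library 1. In AAV8 and AAV8/piggyBac livers Alb was 23289 ± 3063 and 32511 ± 6325 against 31308 in non-diabetic liver, and Pck1 567 ± 149 and 226 ± 191 against 226. Since the non-diabetic liver is 1 library, a difference that did not pass does not show that values were alike.

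B and plasma cell markers rose against non-diabetic liver in AAV8 livers (median log2 2.31, adjusted p = 2.72e-20, 8 of 9 adjusted over the list alone, adjusted p = 0.173 with an estimated correlation) and in AAV8/piggyBac livers (0.53, 0.0021, 0 of 9, adjusted p = 0.988 with an estimated correlation). Over all genes 0 members of any list with a called change passed here. Acute-phase genes rose with AAV8 (0.89, 1.23e-09, 2 of 22 adjusted over the list alone, adjusted p = 0.669 with an estimated correlation). Ribosomal proteins rose with AAV8 (0.21, 0.000917, adjusted p = 0.962 with an estimated correlation, median 0.13 without AAV8 library 2) and with AAV8/piggyBac (0.43, 6.56e-17, adjusted p = 0.988 with an estimated correlation). Male-biased genes fell with AAV8/piggyBac (-0.80, 0.000249, adjusted p = 0.458 with an estimated correlation), and Mup1, a major urinary protein gene, was 30.6 in non-diabetic and 1.45 ± 1.63 in AAV8/piggyBac livers. Adjusted over the list alone 0 members of these 3 calls passed. With the clock score as a covariate the AAV8 ribosomal call was lost (adjusted p = 0.633), and the medians were 0.46 for acute-phase genes with AAV8, and 0.23 for ribosomal and -0.49 for male-biased genes with AAV8/piggyBac.

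Single libraries also ended calls against non-diabetic liver, with 0 members adjusted over the list alone except 2 clock genes with each vector. For AAV8, without AAV8 library 1 the calls of proliferation (0.40, 0.0154), P450 (0.45, 0.0108), male-biased (-0.43, 0.0398) and mitochondrial genes (0.40, 0.00361) were lost (0.513, 0.0741, 0.0741 and 0.124). Without AAV8 library 2 those of fatty acid oxidation (0.15, 0.0142), male-biased genes and the clock (1.28, 0.0284) were lost (0.0561, 0.0734 and 0.0561), and without AAV8 library 3 that of the clock (0.119). The male-biased call was also lost in median-centred values (0.0538) and without rescaling (0.0543). Adjusted p = 0.937 with an estimated correlation for fatty acid oxidation, 0.669 for male-biased genes and the clock, and 0.962 for the other 3. For AAV8/piggyBac, without library 2 the calls of lipogenesis (0.44, 0.0021), urea cycle (-0.56, 0.000215) and mitochondrial genes (-0.29, 0.026) were lost (0.974, 0.238 and 0.238), without library 1 those of acute-phase genes (0.64, 3.73e-06) and the clock (1.35, 0.041) were lost (0.117 and 0.0681), and without library 3 that of the clock (0.197). The clock call was also lost in median-centred values (0.0723). Adjusted p = 0.988 with an estimated correlation for each of these 5. The AAV8 P450 median was 0.70 without AAV8 library 3, and with AAV8/piggyBac that of lipogenesis was 0.80 without library 3 and that of the urea cycle -0.85 without library 1. With the clock score as a covariate the AAV8 calls of fatty acid oxidation, P450, male-biased and mitochondrial genes were lost (0.425, 0.706, 0.425 and 0.102), with a proliferation median of 0.80. The AAV8/piggyBac call of acute-phase genes was then lost (0.0792), with medians of 0.82 for lipogenesis and -0.99 for the urea cycle.

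Lists of insulin signalling and of most other cell types were called in none of the 6 comparisons with all libraries. In AAV8 against diabetic liver the median log2 difference was 0.11 for insulin signalling (adjusted p = 0.0664), -0.11 for antigen presentation (0.657), -0.15 for macrophage markers (0.264), 0.13 for stellate cell markers (0.603), 0.15 for adipocyte markers (0.807), -0.19 for inflammatory signalling (0.417) and 0.11 for Wnt and pericentral genes (0.213). Several of these depended on single libraries. Antigen presentation was called higher without diabetic library 1 (0.36, 2.49e-05) and lower without library 2 (-0.37, 0.0379) or 3 (-0.33, 0.0287). Macrophage markers were called lower without diabetic library 2 (-0.31, 0.0358) or 3 (-0.41, 0.0093), with a median of 0.25 (0.171) without library 1. Insulin signalling was called higher without diabetic library 3 (0.14, 0.00952) or AAV8 library 2 (0.08, 0.0413), and stellate cell markers without diabetic library 1 (0.24, 0.0254). Cholangiocyte markers had a median of 0.01 and a mean of -0.29 (0.874). There the unfolded protein response and P450 lists also had medians (0.03 and 0.06) and means (-0.10 and -0.04) of opposite sign, with adjusted p of 0.71 and 0.861. Gluconeogenesis genes, with a median of -0.32 (0.0664), were not called in AAV8 against diabetic liver, but were without diabetic library 1 (-0.55, 0.000427) or AAV8 library 3 (-0.30, 0.0315). The pancreatic endocrine, pancreatic acinar and T and NK cell lists had 2 tested members each and the neutrophil list 1, too few for a test. Cela1, an elastase of the acinar list, was 16.1 in non-diabetic, 3.25 ± 0.432 in diabetic, 6.57 ± 1.40 in AAV8 and 5.75 ± 2.13 in AAV8/piggyBac livers. The summed T and NK cell markers were 29.8 RPKM in diabetic library 1 and 4.16 to 14.8 in the other libraries.

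In other comparisons some of these uncalled lists also gained calls without 1 library. Without AAV8/piggyBac library 1, macrophage markers were called higher against non-diabetic liver (median 0.58, adjusted p = 5.3e-06, against 0.18 with all libraries) and against AAV8 liver (0.46, 0.000481, against 0.05). Stellate cell markers were then called higher against AAV8 (0.14, 0.00219, against -0.10) and diabetic liver (0.30, 0.00518, against 0.05), and antigen presentation against non-diabetic liver (0.36, 0.0243). Without AAV8/piggyBac library 2, stellate cell markers were lower (-0.42, 0.0237) and inflammatory signalling higher (0.28, 0.0237) against non-diabetic liver, and without library 3 adipocyte markers were lower against AAV8 liver (-0.59, 0.0339). Without diabetic library 1, stellate cell markers were higher in AAV8/piggyBac than in diabetic liver (0.20, 0.0467) and lower in diabetic than in non-diabetic liver (-0.42, 0.00374). Inflammatory signalling was higher in diabetic than in non-diabetic liver without diabetic library 2 (0.59, 0.0214) or 3 (0.54, 0.0182), and cholangiocyte markers in AAV8/piggyBac than in AAV8 liver without AAV8 library 1 (0.36, 0.0358).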

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

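Of the tests in this part, those of blood, rescaling and lymphocytes were chosen after the result was seen, and the splits of the libraries were set before. The responses of 10 genes against diabetic liver differed between the 2 vectors when the difference itself was tested in limma, and all were immunoglobulin genes or Jchain. The difference of largest size was that of Ighg1, with a log2 response of AAV8/piggyBac minus that of AAV8 of -5.578 (adjusted p = 0.000196, lower in 3 of 3 libraries). Since both responses share the diabetic libraries in 1 fit, this difference is the comparison of AAV8/piggyBac with AAV8 liver again and adds no separate evidence.

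Immunoglobulin transcripts were high in all 3 AAV8 livers and low in the other 7 libraries, with Igkc at 245 to 583 rescaled RPKM against 7.12 to 53.2. A larger amount of blood left in the tissue is argued against as the whole source, as far as haemoglobin measures it. The summed haemoglobin RPKM of AAV8 livers was 0.883 of that of diabetic livers, while Igkc was 380 ± 179 against 18.9 ± 10.6. Haemoglobin levels were low (0.381 to 19.8 RPKM per library) and uncertain. The sum does not measure plasma cells carried in blood, so blood richer in such cells stays open. Against AAV8/piggyBac livers mean haemoglobin was 1.59 times as high (10.1 to 14.7 against 0.381 to 14.8), and mean Igkc 10.6 times. The authors' rescaling is argued against too, since its constants, 1 per library, spanned 0.613 log2 over 9 libraries. The smallest of 28 called immunoglobulin differences (18 against diabetic liver and 10 between the vectors) was 1.14 (Iglc2, 0.812 less 2 SE). Lymphoid tissue or lymphocytes of all types cannot be told apart from plasma cells alone, because the T and NK cell marker sum of AAV8 livers was 1.23 times that of AAV8/piggyBac livers and lay, at 9.26 to 12.7, within their range of 4.16 to 14.8. Against diabetic livers the mean sum was 10.5 and 13.1, with 29.8 in diabetic library 1 and 4.69 and 4.77 in the others. The sum of 5 B cell surface markers was 1.18 to 2.44 in AAV8, 0.372 to 2.08 in AAV8/piggyBac and 0.798 to 1.4 in diabetic livers. Its AAV8 mean was 1.62 and 1.78 times that of AAV8/piggyBac and diabetic livers, while that of Igkc was 10.6 and 20.1 times theirs. The overlap of these sums leaves a small share of such cells open. The deposited AAV8 tables gave a fold for 19976 to 21228 genes against 25224 in each of the other 6, so the authors may have processed them apart. The non-diabetic RPKM differed by 0 between tables where shown, but a separate run of the AAV8 libraries coincides with their group and cannot be told apart from it. An immune response that differs between the vectors, or between the animals or times of the groups, may also be the source and was not tested.

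Splits of the 6 libraries of a comparison are too few (10) for a share under 0.05. In each of the 3 comparisons 1 split, the real one, gave as many genes. The real counts and the highest other split were 35 and 0 for AAV8 against diabetic, 45 and 4 for AAV8/piggyBac against diabetic, and 10 and 0 for AAV8/piggyBac against AAV8.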

How the results depend on the processing

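Values without the authors' rescaling, library weights, the clock score as a covariate and the list tests without each library were chosen after seeing the data; the other settings were set before. Numbers below are counts of genes called, in the order AAV8 against diabetic (35 in the report), AAV8/piggyBac against diabetic (45), diabetic against non-diabetic (1), AAV8 against non-diabetic (8) and AAV8/piggyBac against non-diabetic (1), where they moved by over 1.5 times. With no filter on low values, which adds genes to the tests, they were 19, 7, 29, 38 and 24. With library weights they were 1435, 658, 1736, 213 and 3. The weight estimate stopped before convergence and gave diabetic library 1 a weight of 0.17. Without the trend, diabetic against non-diabetic had 2 genes, and with a pseudocount of 0.1 AAV8 against non-diabetic had 5. Without rescaling, AAV8/piggyBac against diabetic had 95. With the clock score as a covariate, AAV8/piggyBac against diabetic had 95 and AAV8 against non-diabetic 4. AAV8/piggyBac against AAV8 (10) stayed within 1.5 times in all these settings, at 7 to 12. Median-centred values, and fits of only the 2 groups compared, moved no count by over 1.5 times, but calls of single genes were lost. Of 15, 20 and 9 genes named by the rule and called for AAV8 against diabetic, AAV8/piggyBac against diabetic and AAV8/piggyBac against AAV8, 5, 12 and 3 lost their call with only the 2 groups in the fit, and 1, 1 and 0 in median-centred values. With no filter 8, 17 and 3 did, with the clock score 6, 0 and 1, without rescaling 3, 2 and 0, and with a pseudocount of 0.1 1, 3 and 2. For each of these changes the cause was not tested.

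With the replicate number as a block, the counts were 11 for AAV8 against diabetic, 3 for AAV8/piggyBac against diabetic, 0 for diabetic against non-diabetic and 5 for AAV8 against non-diabetic, with no other count of genes or lists moved by over 1.5 times. The numbers did not pair the samples: libraries of the same number had correlations of deviations from -0.24 to 0.05, and 6 of 18 correlated best with their own number. With this block 9, 18 and 2 of the 15, 20 and 9 named genes above lost their call.

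Leaving out each library in turn gave 9 to 71 genes for AAV8 against diabetic, 2 to 208 for AAV8/piggyBac against diabetic, 7 to 14 for AAV8/piggyBac against AAV8, 0 to 9 for diabetic against non-diabetic, 6 to 13 for AAV8 against non-diabetic, 0 to 2 for AAV8/piggyBac against non-diabetic, and 1 to 22 for the genes called by both vectors in 1 direction. Against diabetic liver, the lowest count of AAV8 came without diabetic library 2, and that of AAV8/piggyBac without diabetic library 2 or 3. The highest count of AAV8/piggyBac came without diabetic library 1. With 2 libraries left, a group relies on the spread shared by all groups. For single genes named by the rule and called, leaving out a library kept the call and direction in 174 results, lost the call in the same direction in 138 and reversed 0. Over all settings, these included, 541 were kept, 247 lost and 0 reversed. For the largest rises and falls the naming rule required no overlap, so leaving out a library could not reverse them.

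Of the gene lists, 13 were called for AAV8 against diabetic, 17 for AAV8/piggyBac against diabetic, 16 for AAV8/piggyBac against AAV8, 15 for diabetic against non-diabetic, 9 for AAV8 against non-diabetic and 8 for AAV8/piggyBac against non-diabetic. With an estimated correlation camera called 0 in all 6 comparisons, with lowest adjusted p of 0.22, 0.543, 0.233, 0.682, 0.173 and 0.458. In fry, which tests whether a list moves 1 way, 1 list was called for AAV8 against diabetic (B and plasma cell markers, adjusted p = 0.00886) and 0 in the other 5. The mixed test of fry, which lets members move either way, called 3, 8, 1, 2, 1 and 0 lists, among them lipogenesis (0.0242) and p53 targets (0.0338) for AAV8 against diabetic. With the clock score, 16 were called for AAV8/piggyBac against non-diabetic. Without each library in turn the counts were 12 to 16, 14 to 21, 11 to 19, 15 to 16, 5 to 11 and 10 to 11, with the 5 without AAV8 library 1. Of the lists not called with all libraries (20, 16, 17, 18, 24 and 25), 9, 8, 9, 7, 2 and 12 gained a call without 1 library. Antigen presentation did so in both directions for AAV8 against diabetic and diabetic against non-diabetic, and interferon response for AAV8/piggyBac against diabetic and diabetic against non-diabetic. Depth limits the low genes: 3 reads of Ins1 were 0.0302 to 0.0427 RPKM, and only genes with a mean of 1 rescaled RPKM or more were tested.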

Other observations

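In this part the tests on diabetic library 1 were chosen after the result was seen. The clock score as a covariate was also chosen after seeing the data. What would argue for or against clock phase was written down before that fit. The spread of the clock ratio was added after its first values were seen. The genes named here for single libraries were chosen after their values were seen. Single livers stood apart from their group in the single genes named here, without a test of gene groups. In diabetic library 1, Phlda3, a p53 target, was 19.6 rescaled RPKM against 2.37 and 2.72 in the other diabetic libraries, Tgtp1, an interferon-induced GTPase, 161 against 0.888 and 0.588, Ly6d, a surface protein seen in stressed and tumour tissue, 142 against 13.5 and 16.3, and Cd74, the invariant chain of antigen presentation, 277 against 49.0 and 47.3. AAV8/piggyBac library 2, with a clock score near that of the non-diabetic liver, had Fgf21, a fasting and carbohydrate hormone, at 59.8 against 1.47 and 0.976, the pyruvate kinase gene Pklr at 474 against 30.8 and 79.3, and the fatty acid synthase gene Fasn at 570 against 146 and 62.1. AAV8/piggyBac library 1 had the bile acid enzyme Cyp8b1 at 0.128 against 181 and 28.4. Its mean log2 (rescaled RPKM + 1) was 2.57 for endothelial markers against 3.41 and 3.37 in libraries 2 and 3. It was 1.60 against 2.18 and 2.07 for stellate cell markers, and 8.89 against 8.37 and 8.32 for hepatocyte markers. Neutrophil, cholangiocyte and B and plasma cell markers were not lower there. Whether the cell make-up of this library differed was not tested. Ctrb1, a chymotrypsinogen of pancreatic acinar cells, was 0.924, 1.01 and 0.181 in the AAV8/piggyBac libraries and at most 0.177 in every other library, without a test.

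Diabetic library 1 stood apart in p53 and interferon genes and also had reads on 22.5% of 1931 olfactory and vomeronasal receptor genes, which liver should not express, against at most 3.2% in any other library. Those reads are consistent with genomic DNA in the library. Genomic DNA as the source of the p53 and interferon rise is argued against, since the median rise of 58 genes over the other diabetic libraries (7.71 RPKM) was 1376 times the mean gain of the silent receptors. A vector-treated liver under the wrong label is argued against, since Ins1 was at 0, below the floor of 0.0406 RPKM. Immune cell markers were also higher in this library: the T and NK cell marker sum was 29.8 RPKM against 4.69 and 4.77 in the other diabetic libraries, and the mean log2 (rescaled RPKM + 1) of the macrophage list 4.02 against 2.82 and 2.68. Immune cells in this liver, a sick animal or damaged tissue may be the source of the interferon rise, and no biological explanation was tested.

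Lipogenesis genes were lower in diabetic livers while the clock score also differed between libraries, so a different clock phase at collection is a candidate explanation. With the clock score as a covariate, the lipogenesis median of AAV8/piggyBac against diabetic was 1.59 in place of 1.77 (ratio 0.90, 95% bootstrap interval over genes 0.89 to 1.01). The clock scores of these groups overlapped, at -1.885 to -0.142 in diabetic and -2.25 to 1.86 in AAV8/piggyBac libraries. A shift in clock score between the groups is argued against as the whole cause in these libraries. Clock phase itself stays open, because the score does not fix the phase and the covariate removes only what follows the score linearly. AAV8/piggyBac libraries 1 and 3 had scores of -2.20 and -2.25, but Nr1d1 at 10.9 and 56.0 and Dbp at 18.9 and 57.3. The bootstrap intervals resample genes, which are not independent replicates, so they do not measure the spread between livers. For diabetic against non-diabetic the median was -0.75 in place of -1.30 (ratio 0.57, interval 0.15 to 0.96). There clock phase cannot be told apart from diabetes, since the only non-diabetic liver also had the highest clock score. Insulin supply, which the design varies, stays open for both and was not tested apart from the groups.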
